A study of Mus musculus with 72 samples.

How the data were processed

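The data were 3′ mRNA sequencing libraries made from the livers of male C57BL/6J mice. The 72 libraries came from 4 feeding paradigms, 6 zeitgeber times (ZT, hours after lights on, in a 12 h light and 12 h dark day) and 3 replicates, so that each paradigm and time held 3 libraries and each paradigm 18. Per the labels the paradigms were night-restricted feeding, ad libitum feeding, arrhythmic feeding, and arrhythmic feeding in animals that had not fully adapted, here called incompletely adapted arrhythmic feeding. How food was timed and how adaptation was judged are not given in the sources used here. The labels do not say that replicates came from separate animals, so the p-values measure the spread between these samples. Per the submitters' protocol notes, RNA was extracted with TRIzol and libraries were prepared with the Lexogen QuantSeq 3′ kit. Per the submitters' processing notes, reads were aligned with STAR 2.4.2a, and the builds mm10 and GRCm38.p5 were named. The counting tool, its strand setting and its annotation release are not given in the sources used here.

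The authors deposited 2 tables. The first held raw read counts, 1 column per library, for 51912 Ensembl genes. The second was named TPM, but the deposited values were CPM: each value equalled the library's CPM computed from the raw counts to within 5.09e-11, with no term for gene length. That CPM table, as the authors deposited it, kept 11508 genes, and these were the genes above 1 CPM in at least 36 libraries. All 72 columns were assigned to a paradigm, time and replicate, and 0 columns were left out. Gene symbols, positions and transcript sequences were taken from the GENCODE M21 annotation of GRCm38. It gave a symbol for 51719 gene identifiers, and the 193 without one held 0.00309 percent of counts.

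Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were left out with filterByExpr over the 24 groups of paradigm and time, which left 12712 genes. Library totals were scaled by TMM, and a single quasi-likelihood model with robust dispersion estimates was fitted to all 72 libraries, with a mean, a cosine and a sine coefficient per paradigm at a period of 24 h. A gene was called rhythmic in a paradigm when the F test of its cosine and sine coefficients passed a false discovery rate of 0.05 (Benjamini-Hochberg over all genes tested). A rhythm difference between paradigms was called by the F test that both coefficients were equal, and a mean level difference by the test of the paradigm means over the day. The range of a gene is the fitted peak-to-trough difference on the log2 scale, and its standard error (SE) and that of the peak time came from the delta method. A fitted range cannot be negative, so noise alone gives a range above 0. Levels are in CPM with the standard deviation (SD) between libraries.

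The comparisons were arrhythmic against night-restricted, arrhythmic against ad libitum, night-restricted against ad libitum, and incompletely adapted arrhythmic against arrhythmic feeding. Ratios of ranges between a pair of paradigms were taken in genes chosen in another paradigm, so that neither of the pair was used to choose them. They were compared with random reassignments of the paradigm labels within each time. The spread between libraries was the median over genes of the SD of log2 CPM at each time, compared over the 6 times by an exact sign-flip permutation test.

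Gene lists were fixed before the data were examined, as were the design of the tests, the rule for named genes and the alternatives, except those named below as added. The pathway lists were core clock, clock-controlled liver output, lipogenesis, cholesterol synthesis, gluconeogenesis and fasting, PPARA targets and ketogenesis, glycolysis and glycogen, bile acid and xenobiotic metabolism, amino acid catabolism and urea cycle, ribosome biogenesis, ER chaperones and unfolded protein response, integrated stress response, heat shock proteins, cold-inducible RNA-binding proteins, glucocorticoid-responsive, acute phase and inflammation, male-biased liver genes, female-biased liver genes, growth hormone and IGF axis, immediate early genes, mitochondrial respiratory chain, and cell cycle. The cell type lists were pericentral hepatocytes, periportal hepatocytes, Kupffer cells and macrophages, endothelial cells, stellate cells and fibroblasts, cholangiocytes, T and NK cells, B and plasma cells, neutrophils, erythroid cells, pancreatic acinar cells, and adipocytes. Members past the test were counted over all genes and adjusted over the list alone. Lists with at least 5 tested members were tested by mean level with camera from limma 3.58.1, with a preset correlation between genes of 0.01 and again with an estimated correlation. For rhythm, the median ratio of ranges of a list was placed among 10000 random lists of the same size drawn from genes rhythmic under ad libitum feeding.

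The rule for named genes took the tested core clock genes, the 10 genes of smallest p with lower and the 10 with higher range for each rhythm difference, and the 10 genes with the largest rise and the 10 with the largest fall for each mean difference. It also took up to 4 members of smallest p for each list and comparison, and the 10 genes of largest range in each paradigm. Outside the lists, named genes had a mean of at least 10 CPM, predicted genes were left out, and genes named for a mean difference had changed in the same direction at each of the 6 times. Srebf1, a member of the lipogenesis list outside the rule, was named after its values were seen. Some genes that the rule takes are not reported here.

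For each library, the slope of its log2 CPM deviation from the gene means on the GC content of the last 300 bases of each gene's transcripts was computed, per 10 percentage points, and is called the GC slope. It is estimated from the expression values it is then used to adjust. After the data had been examined, these alternatives were added: the GC slope as a covariate (also from the last 100, 200 or 500 bases, and with the replicate number), leaving out 5 libraries with a GC slope over 2 robust SD from the median, leaving out each single library, and testing only the genes of the authors' CPM table. Covariates made from principal components were also tried and were not used.

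The alternatives planned beforehand were DESeq2 size factors or upper quartile scaling in place of TMM, no filter on counts or a mean of at least 10 CPM, the DESeq2 1.42.0 likelihood ratio test, limma on log2(CPM + 1) and log2(CPM + 0.1), time as a factor, a fit of only the libraries compared, the replicate number as a block, a change or range of at least 1.5-fold, a false discovery rate of 0.01, ranges projected on a fixed phase, and leaving out all libraries of a replicate number of a paradigm. The closing section gives the counts that they moved by over 1.5 times, ranges with libraries left out, and range differences that changed sign.

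Total counts per library ran from 4342026 to 12286021. The pipeline was tested on simulated data with the same library totals and 12712 genes, in which the changed genes had a mean of at least 10 CPM. Of 50 genes given a rhythm under night-restricted feeding, 12 were called at a log2 range of 1 and 50 at a log2 range of 2. For a rhythm difference between arrhythmic and night-restricted feeding, 0 of 50 genes were called at a log2 range of 1 and 38 at a log2 range of 2. For a mean difference between these paradigms, 38 of 50 genes were called at 1.5-fold and 50 at 2-fold. Of 12612 unchanged genes, 5 were called rhythmic, 0 for a rhythm difference and 5 for a mean difference. The simulated genes varied independently of each other. They lacked the main axis of the real libraries and the tie between like replicate numbers, both described below. Few genes were given a change, which makes the adjusted p stricter than where many genes change. The counts of genes recovered and of false calls therefore need not hold for the real data. The other comparisons were not simulated. Reads carried no molecular identifiers in the tables, so counts are reads and not molecules.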

Results

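The series title sets rhythmic food intake against the hepatic circadian clock as drivers of rhythmic gene expression. Liver mRNA was counted in 72 libraries, 18 for each of night-restricted, ad libitum, arrhythmic and incompletely adapted arrhythmic feeding, at ZT02, ZT06, ZT10, ZT14, ZT18 and ZT22 with 3 libraries each. Total counts per library ran from 4342026 to 12286021 (median 6453747) under night-restricted feeding, from 6701379 to 11167161 (median 8375853) under ad libitum feeding, from 5628818 to 7806974 under arrhythmic feeding, and from 6017962 to 7972905 under incompletely adapted arrhythmic feeding. Mitochondrial transcripts took 4.27 ± 1.2 percent of counts (SD, n = 18) under night-restricted, 4.39 ± 0.794 under ad libitum, 4.29 ± 0.637 under arrhythmic and 4.61 ± 0.818 under incompletely adapted arrhythmic feeding.

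The libraries differed along a main axis. The first principal component of the most variable genes held 53.2 percent of their variance and the second 9.7 percent. The first component followed the GC slope, the trend of a library's deviations on the GC content of transcript 3′ ends, with Pearson r = 0.949 and Spearman rho = 0.918 over 72 libraries (permutation p = 1e-05 for both, the smallest these permutations can give; Benjamini-Hochberg adjusted over 11 relations, 1.2e-05 and 1.4e-05). Pearson r was 0.937 without the 2 libraries farthest from the median, and 0.973, 0.924, 0.939 and 0.957 within night-restricted, ad libitum, arrhythmic and incompletely adapted arrhythmic feeding. The GC slope had a mean of 0.0761 ± 0.206 (SD, n = 18) under night-restricted, 0.011 ± 0.135 under ad libitum, -0.019 ± 0.14 under arrhythmic and -0.0681 ± 0.191 under incompletely adapted arrhythmic feeding. The 5 libraries farthest out were night-restricted replicate 1 at ZT02 (0.412), ZT06 (0.414), ZT18 (0.309) and ZT22 (0.477), and incompletely adapted replicate 1 at ZT10 (-0.364). The counts of rhythmic and of differing genes over all genes are therefore also given below with the GC slope as a covariate and without these 5 libraries, and most counts within lists with the covariate, both chosen after the data had been seen.

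**Figure D1:**
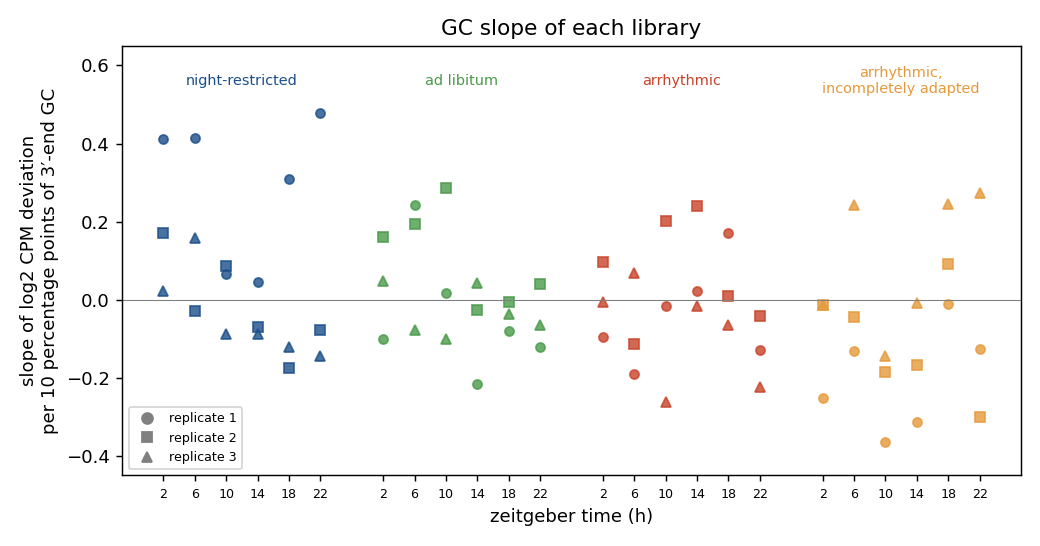
GC slope of each of the 72 libraries (log2 CPM deviation per 10 percentage points of GC in the last 300 bases) against zeitgeber time in hours, coloured by feeding paradigm, with marker shape for the replicate number. Night-restricted replicate 1 stood highest, at 0.477 at ZT22.

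Of 19 core clock genes tested, 16 were called rhythmic in all 4 paradigms. Dbp, a clock-controlled transcription factor, had a fitted log2 range of 5.44 ± 0.49 (SE) peaking at ZT 9.4 under night-restricted feeding, 6.54 ± 0.50 at ZT 10.1 under ad libitum feeding, 4.79 ± 0.47 at ZT 8.1 under arrhythmic feeding, and 5.07 ± 0.47 at ZT 8.9 under incompletely adapted arrhythmic feeding. Nr1d1, which encodes the nuclear receptor REV-ERBα, peaked between ZT 5.6 and ZT 6.9 in the 4 paradigms, with ranges from 3.56 ± 0.51 under arrhythmic to 5.74 ± 0.55 under ad libitum feeding. Arntl, which encodes the clock activator BMAL1 (ENSMUSG00000055116.8, GRCm38 chromosome 7, 113207465 to 113314126), was in opposite phase, with a range of 4.88 ± 0.86 at ZT 21.6 under night-restricted and 3.32 ± 0.75 at ZT 21.5 under arrhythmic feeding. Its level under night-restricted feeding was 0.172 ± 0.0516 CPM at ZT10 and 8.68 ± 5.98 CPM at ZT22 (SD, n = 3), close to the floor at its trough. Per2, a clock repressor, had ranges of 4.22 ± 0.42 at ZT 14.2, 2.98 ± 0.41 at ZT 15.3, 2.37 ± 0.41 at ZT 11.8 and 2.82 ± 0.41 at ZT 12.4 in the same order of paradigms.

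Of these 19 clock genes, 17 were rhythmic under night-restricted, 18 under ad libitum, 16 under arrhythmic and 16 under incompletely adapted arrhythmic feeding (18, 18, 17 and 17 when adjusted over the list alone; 17, 18, 16 and 16 with the GC slope as a covariate). Against ad libitum feeding, all 16 clock genes rhythmic in both peaked earlier under arrhythmic feeding, by a median of -1.19 h (from -3.43 to -0.204 h), and 15 had a smaller range, with a median ratio of 0.836. Of the 19, the rhythm difference was called for 0 over all genes, for 9 when adjusted over the list alone, and for 1 over all genes with the GC slope as a covariate. Against night-restricted feeding, 12 of 16 peaked earlier under arrhythmic feeding (median -0.621 h) and 12 had a smaller range (median ratio 0.793). The difference was called for 4 clock genes, Cry1 (adjusted p = 0.00903), Per2 (0.0107), Hlf (0.0147) and Bhlhe40 (0.0463), and for 7 when adjusted over the list alone. It was called for 3 with the GC slope as a covariate, where Bhlhe40 was not called (adjusted p = 0.226). Bhlhe40, a transcriptional repressor of the clock, had a range of 2.03 ± 0.44 at ZT 14.9 under night-restricted feeding and 0.87 ± 0.44 under arrhythmic feeding, where it was not called rhythmic (adjusted p = 0.542). Between night-restricted and ad libitum feeding 16 of 17 peaked earlier under night-restricted feeding (median -0.661 h), and between the arrhythmic paradigms 5 of 16 peaked earlier in the incompletely adapted one (median 0.337 h), with 0 called in either comparison.

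**Figure D2:**
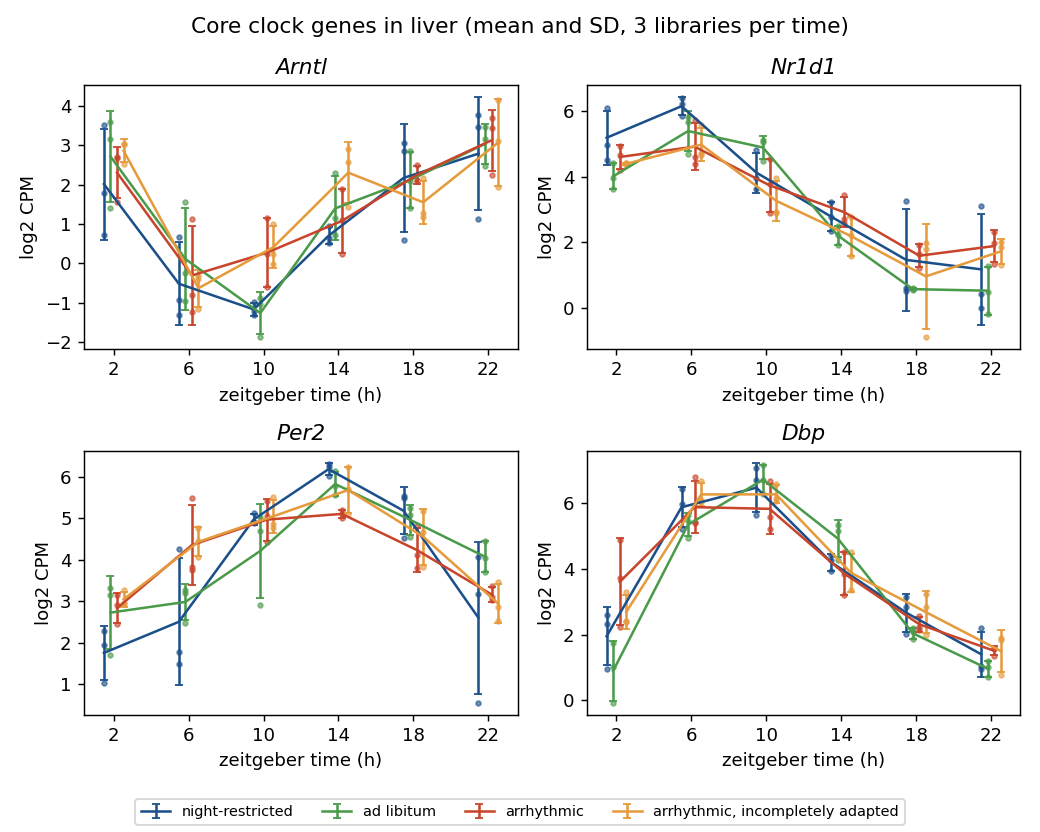
Levels of Arntl, Nr1d1, Per2 and Dbp (log2 CPM) against zeitgeber time in hours, coloured by feeding paradigm, with points for libraries and lines for the mean ± SD of 3 libraries at each time. Dbp peaked between ZT 8.1 and ZT 10.1 in the 4 paradigms.

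Of 12712 genes, 3801 were called rhythmic under night-restricted, 951 under ad libitum, 429 under arrhythmic and 462 under incompletely adapted arrhythmic feeding. Among genes with a mean of at least 10 CPM, the largest ranges outside the core clock under night-restricted feeding were those of Rgs16, a regulator of G protein signalling (7.01 ± 0.77 at ZT 8.5), Alas1, the rate-limiting enzyme of heme synthesis (4.67 ± 0.58 at ZT 13.6), and Tubb2b, a tubulin (3.95 ± 0.97 at ZT 20.7). Usp2, a clock-controlled deubiquitinase, was among the 10 such genes of largest range in each of the 4 paradigms, with ranges from 3.75 ± 0.51 under incompletely adapted arrhythmic to 4.87 ± 0.52 under ad libitum feeding. Under arrhythmic feeding the largest ranges of such genes included those of Lpin1, which encodes a phosphatidate phosphatase (3.75 ± 0.47 at ZT 12.6), Upp2, a uridine phosphorylase (2.92 ± 0.34 at ZT 11.7), and Chka, a choline kinase (2.64 ± 0.37 at ZT 21.8). The median range of rhythmic genes was 1.08 under night-restricted, 1.20 under ad libitum, 1.25 under arrhythmic and 1.21 under incompletely adapted arrhythmic feeding, and 46.7, 47.3, 63.4 and 63.4 percent of them peaked in the dark phase.

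The counts of rhythmic genes depended on the libraries and on their composition. At an unadjusted p under 0.05 the counts were 5496, 2847, 1757 and 1756 for night-restricted, ad libitum, arrhythmic and incompletely adapted arrhythmic feeding, in that order. With the GC slope as a covariate the counts were 4226, 1511, 817 and 829, of which 3122, 922, 428 and 453 were also called without it. Without the 5 libraries of extreme GC slope they were 3004, 1522, 573 and 467. With each paradigm fitted to its own libraries they were 1860, 865, 398 and 333, and with time as a factor of 6 levels 1741, 509, 212 and 300. Leaving out the 6 libraries of a replicate number gave 2242 to 2842 genes under night-restricted, 253 to 833 under ad libitum, 180 to 211 under arrhythmic and 183 to 306 under incompletely adapted arrhythmic feeding. Each gene was called rhythmic by a test within its paradigm, so a gene called in 1 paradigm alone is not by that shown to differ between paradigms. The tests of that difference follow.

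**Figure D3:**
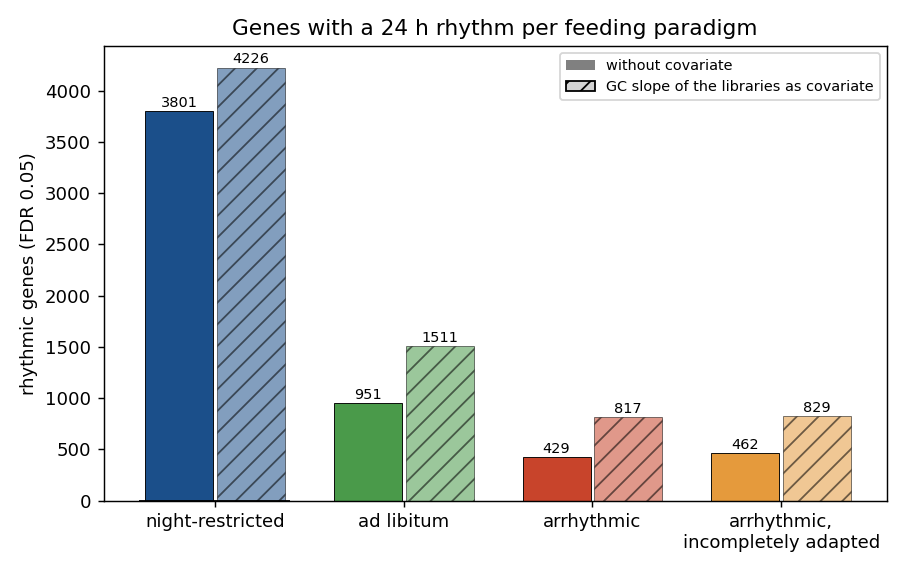
Number of genes called rhythmic at a false discovery rate of 0.05 in each feeding paradigm (y axis, from 0; solid bars) and with the GC slope of the libraries as a covariate (hatched bars). The counts were 3801, 951, 429 and 462, and 4226, 1511, 817 and 829 with the covariate.

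Genes rhythmic in 1 paradigm were often rhythmic in another. The 4 paradigms shared 196 rhythmic genes, 16 of which were core clock genes. Night-restricted and ad libitum feeding shared 794 where independent lists would share 284.4. Night-restricted feeding shared 330 with arrhythmic feeding (128.3 if independent) and 387 with incompletely adapted arrhythmic feeding (138.1). Ad libitum feeding shared 266 with arrhythmic feeding (32.09) and 316 with incompletely adapted arrhythmic feeding (34.56). The arrhythmic paradigms shared 236 (15.59). With the GC slope as a covariate the 4 paradigms shared 381 genes. All paradigms were tested in a single fit with a shared estimate of the spread. Genes of high level or small spread are thus more readily called in each paradigm. The counts for independent lists do not allow for this.

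The comparison of arrhythmic with night-restricted feeding asks what changes when the daily timing of food is removed. Ppp1r3b, Alas1, Tfrc and Mid1ip1 were called rhythmic under night-restricted feeding and not under arrhythmic feeding (adjusted p = 0.137, 0.653, 0.199 and 0.154), though Tfrc and Mid1ip1 were called there with the GC slope as a covariate (adjusted p = 0.0244 and 0.0483). Ppp1r3b, a glycogen-targeting subunit of protein phosphatase 1 (ENSMUSG00000046794.9, chromosome 8, 35375739 to 35388139), went from 187.9 ± 87.9 CPM at ZT06 to 1908 ± 399 CPM at ZT18 under night-restricted feeding (SD, n = 3), and lay between 718.7 ± 125 CPM at ZT02 and 1597 ± 123 CPM at ZT14 under arrhythmic feeding. Its fitted range was 3.40 ± 0.30 against 0.98 ± 0.30 (adjusted p of the difference 9.69e-05). Alas1 (ENSMUSG00000032786.16, chromosome 9, 106233455 to 106248654) went from 6.37 ± 1.95 CPM at ZT02 to 171.8 ± 99.7 CPM at ZT14 under night-restricted feeding and lay between 28.8 ± 9.4 CPM at ZT14 and 63.3 ± 20.1 CPM at ZT10 under arrhythmic feeding (adjusted p = 0.000688). Tfrc, the transferrin receptor (ENSMUSG00000022797.15, chromosome 16, 32608920 to 32632794), had a range of 3.50 ± 0.42 peaking at ZT 16.1 against 1.17 ± 0.40 (adjusted p = 0.000195). Mid1ip1, which encodes an activator of acetyl-CoA carboxylase (ENSMUSG00000008035.12, chromosome X, 10715013 to 10719690), had a range of 2.79 ± 0.30 at ZT 16.7 against 0.93 ± 0.30 (adjusted p = 1.64e-06).

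Cholesterol synthesis was the list with the most differences, 12 of 24 genes, 18 when adjusted over the list alone and 13 with the GC slope as a covariate. Its 13 members rhythmic under night-restricted feeding had a mean peak at ZT 21.7 and the 4 rhythmic under arrhythmic feeding one at ZT 10.1. Insig1, a regulator of sterol synthesis (ENSMUSG00000045294.11, chromosome 5, 28071363 to 28078662), had a range of 1.10 ± 0.17 at ZT 20.7 under night-restricted and 0.75 ± 0.16 at ZT 8.8 under arrhythmic feeding and was rhythmic in both (adjusted p of the difference 2.93e-06). Lss, lanosterol synthase, had ranges of 1.75 ± 0.25 and 0.79 ± 0.24 (adjusted p = 0.000195), and Dhcr7, the last enzyme of the pathway, ranges of 1.33 ± 0.23 and 0.58 ± 0.23 (adjusted p = 0.0011). In the lipogenesis list, 9 of 18 genes differed, 13 when adjusted over the list alone and 9 with the covariate. Fasn, fatty acid synthase, had ranges of 2.48 ± 0.48 at ZT 20.6 and 1.61 ± 0.47 at ZT 10.4 (adjusted p = 0.0035). Acly, ATP citrate lyase, had ranges of 1.90 ± 0.32 and 0.85 ± 0.32 (adjusted p = 0.00121). Srebf1, the transcription factor that drives lipogenic genes, had ranges of 2.44 ± 0.60 and 1.39 ± 0.58 (adjusted p = 0.0162).

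Of the glycolysis and glycogen list 6 of 19 genes differed (12 adjusted over the list alone, 4 with the covariate). Among ER chaperones and unfolded protein response genes 13 of 19 were rhythmic under night-restricted, 1 under ad libitum, 1 under arrhythmic and 2 under incompletely adapted arrhythmic feeding (12, 1, 1 and 4 with the covariate), and 8 differed (13 adjusted over the list alone, 7 with the covariate). They included Creld2 (2.10 ± 0.32 and 0.19 ± 0.31, adjusted p = 0.0133), Manf (adjusted p = 0.00216) and Dnajb11 (adjusted p = 0.0102), which encode proteins of the secretory pathway. All 16 heat shock protein genes tested were rhythmic under night-restricted feeding, 12 under ad libitum, 7 under arrhythmic and 7 under incompletely adapted arrhythmic feeding (16, 14, 9 and 10 with the covariate). The difference was called for Dnaja1 (adjusted p = 0.00482) and Chordc1 (adjusted p = 0.0122), and for 4 genes when adjusted over the list alone and 4 with the covariate. Cirbp, a cold-inducible RNA-binding protein, had a range of 2.59 ± 0.25 at ZT 5.1 against 0.96 ± 0.25 at ZT 4.5 (adjusted p = 0.0113), and the other list member, Rbm3, was not called (adjusted p = 0.412). Mt1 and Mt2, metallothionein genes, were the 2 of 14 glucocorticoid-responsive genes that differed (2 with the covariate). Mt1 had a range of 3.63 ± 0.58 at ZT 9.4 under night-restricted feeding and of 1.82 ± 0.59 under arrhythmic feeding (adjusted p = 0.00422). Trib3 and Atf5 differed among 12 integrated stress response genes (adjusted p = 0.0162 and 0.00935; 2 genes with the covariate).

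**Figure D4:**
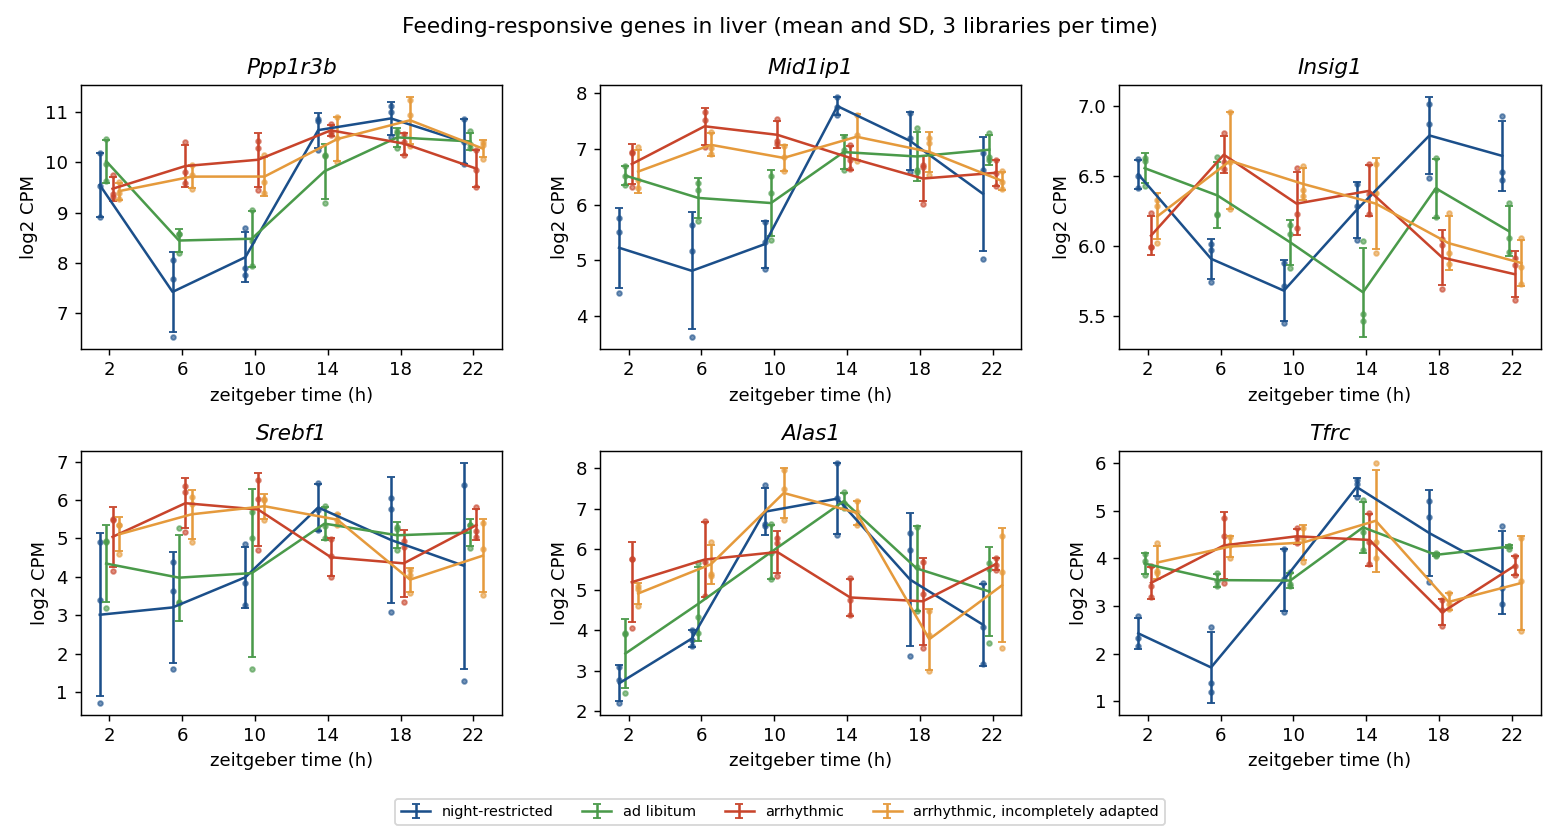
Levels of Ppp1r3b, Mid1ip1, Insig1, Srebf1, Alas1 and Tfrc (log2 CPM) against zeitgeber time in hours, coloured by feeding paradigm, with points for libraries and lines for the mean ± SD of 3 libraries at each time. The fitted range of Ppp1r3b was 3.40 under night-restricted and 0.98 under arrhythmic feeding.

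In all, the rhythm of 495 genes differed between arrhythmic and night-restricted feeding, 461 with a smaller and 34 with a larger range under arrhythmic feeding. Of these, 412 were rhythmic under night-restricted feeding alone, 11 under arrhythmic feeding alone, 20 in neither, and 52 in both, 23 of them with peaks over 4 h apart. The genes with a larger range under arrhythmic feeding included Hsd17b7, an enzyme of cholesterol synthesis (0.45 ± 0.18 and 0.91 ± 0.18, adjusted p = 0.00431), and Vcam1, an adhesion molecule (1.03 ± 0.22 and 1.59 ± 0.22, adjusted p = 0.00641). They also included Foxo1, a fasting transcription factor (0.80 ± 0.15 and 1.07 ± 0.15, adjusted p = 0.0122), Ahcy, a methionine cycle enzyme (adjusted p = 0.00996), Srsf3, a splicing factor (adjusted p = 0.00935), and Adh1, an alcohol dehydrogenase (adjusted p = 0.0268). Thrsp, a lipogenic regulator, also had a larger range (3.05 ± 0.49 against 2.35 ± 0.49, adjusted p = 0.00973), and a smaller one with the GC slope as a covariate (range difference -0.54). Slc35b1, Pex3 and Srsf2 were among the 10 genes of smallest p with a smaller range and a mean of at least 10 CPM (adjusted p = 0.000688, 0.000688 and 0.000782), though the range difference of Srsf2 changed sign in 2 of 57 alternatives. At an unadjusted p under 0.05, 3294 genes differed. With the GC slope as a covariate 424 genes differed, 278 of them also called without it, and 313 differed without the 5 libraries of extreme GC slope.

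Single libraries moved this count by over 1.5 times. It was 220 without night-restricted ZT02 replicate 1, 281 without arrhythmic ZT14 replicate 2, and 292 without night-restricted ZT14 replicate 2. It was 755 without arrhythmic ZT02 replicate 2, 784 without night-restricted ZT06 replicate 2, 798 without night-restricted ZT22 replicate 2, and 809 without night-restricted ZT02 replicate 2. It was 829 without night-restricted ZT22 replicate 3, 851 without night-restricted ZT02 replicate 3, and 1250 without night-restricted ZT18 replicate 1. With time as a factor of 6 levels in place of the cosine 52 genes differed.

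Of clock-controlled liver output genes 11, 10, 8 and 9 of 12 were rhythmic in the 4 paradigms (12, 11, 10 and 10 with the GC slope as a covariate) and Alas1 and Tfrc differed (2 with the covariate). Of 23 PPARA targets and ketogenesis genes 13, 7, 6 and 5 were rhythmic (14, 9, 6 and 7 with the covariate) and 1 differed (4 adjusted over the list alone, 1 with the covariate), Cpt1a, the carnitine palmitoyltransferase of mitochondrial fatty acid import (1.59 ± 0.15 and 0.64 ± 0.15, adjusted p = 0.00879). The counts of differing members were 3 of 17 for gluconeogenesis and fasting (5 adjusted over the list alone, 5 with the covariate), 3 of 25 for ribosome biogenesis (8 and 1) and 2 of 24 for amino acid catabolism and urea cycle (6 and 2). They were 2 of 21 for acute phase and inflammation (2 and 0), 1 of 11 for growth hormone and IGF axis (2 and 1) and 1 of 26 for the mitochondrial respiratory chain (1 and 0). No member differed for bile acid and xenobiotic metabolism (1 adjusted over the list alone), male-biased liver genes, female-biased liver genes, immediate early genes or cell cycle. Among cell type lists, Lect2 of 14 pericentral genes, Ass1 of 13 periportal genes and Cela1, the only pancreatic acinar gene tested, differed. With the covariate Lect2 and Cela1 were not called (adjusted p = 0.0633 and 0.0687), and the range difference of Lect2 changed sign in 30 of 57 alternatives. No member differed of the lists for Kupffer cells and macrophages, endothelial cells, stellate cells and fibroblasts, cholangiocytes, T and NK cells, B and plasma cells, neutrophils, erythroid cells or adipocytes. Adjusted over the list alone 2 endothelial, 2 T and NK cell and 1 cholangiocyte members did, and with the covariate 1 cholangiocyte member.

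In genes chosen as rhythmic under ad libitum feeding, the median ratio of the range under arrhythmic to that under night-restricted feeding was 0.558. Of 100 assignments of the paradigm labels 1, the real one, gave a ratio as far from 1. Of the 951 genes chosen, 794 were also rhythmic under night-restricted and 266 under arrhythmic feeding, so the choice may not be neutral between them. The ratio of core clock members was 0.793, above 98.6 percent of random lists of the same size, and that of glucocorticoid-responsive members 0.912, above 98.9 percent. Clock-controlled liver output had a ratio of 0.689 (84.5 percent), PPARA targets and ketogenesis 0.717 (84.5 percent), cholesterol synthesis 0.684 (77.3 percent), glycolysis and glycogen 0.654 (75.4 percent) and heat shock proteins 0.504 (31.2 percent). Measured as the range projected on the ad libitum phase, the ratio of cholesterol synthesis was -0.452, below nearly all random lists (0.01 percent). It rested on the 5 of 24 members rhythmic under ad libitum feeding. Random lists were drawn gene by gene, so the percentile does not allow for correlation between members. They were also not matched for range. Under ad libitum feeding the median range was 2.98 over core clock members and 2.63 over glucocorticoid-responsive members. It was 1.2 over all genes rhythmic there, so these percentiles may reflect larger ranges. In genes chosen under arrhythmic feeding, the ratio of ad libitum to night-restricted feeding was 0.845, with 1 of 100 assignments as far from 1. The lowest other ratio was 0.8645, so with this margin chance is not excluded. The ratio ran from 0.799 to 0.895 with a replicate number of a paradigm left out. Noise adds to a fitted range, so a larger spread under night-restricted feeding would lower this ratio and that of arrhythmic to night-restricted feeding.

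Mean levels over the day also differed between arrhythmic and night-restricted feeding. Ulk1, which encodes a kinase that starts autophagy, rose from 164 ± 67.2 to 262 ± 85.6 CPM (SD, n = 18), a log2 change of 0.69 ± 0.14 (SE, adjusted p = 0.00183). Abcd2, a peroxisomal fatty acid transporter, rose by 0.78 ± 0.18 (adjusted p = 0.00616). Cyp2a4, a steroid hydroxylase of female-biased expression, rose by 1.99 ± 0.49 (adjusted p = 0.00944). Cyp2b9, another female-biased P450 gene, changed the other way, by -1.43 ± 0.36 (adjusted p = 0.0126). How reads shared between close paralogs, such as those of the Cyp2, Cyp4a12 and Mup families or Mt1 and Mt2, were counted is not given in the sources used here.

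By list, Elovl6, a fatty acid elongase, rose by 0.82 ± 0.19 and Fads1, a fatty acid desaturase, by 0.39 ± 0.10. They were 2 of 18 lipogenesis genes, of which 2 others fell, Mlxipl (-0.39 ± 0.13) and Dgat2 (-0.42 ± 0.14). In the fit with the GC slope 5 rose and 0 fell, and the list was higher (adjusted p = 0.00366; adjusted p = 0.791 with an estimated correlation). In cholesterol synthesis 2 of 24 fell, Srebf2, the transcription factor of the pathway (-0.36 ± 0.08), and Nsdhl (-0.40 ± 0.12), and 1 with the covariate, where Nsdhl was not called (adjusted p = 0.0549). In the integrated stress response 3 of 12 fell and none rose, Trib3 (-0.80 ± 0.18), Ddit3 (-0.51 ± 0.16) and Atf4 (-0.36 ± 0.10), 4 fell when adjusted over the list alone, and 2 with the covariate, where Ddit3 was not called (adjusted p = 0.198). In the mitochondrial respiratory chain 4 of 26 fell, among them Cox4i1 (-0.56 ± 0.13), 5 when adjusted over the list alone, and 3 with the covariate, where 1 rose. Mt1 fell (-1.28 ± 0.29, adjusted p = 0.00583), as did Cyp8b1, a sterol hydroxylase of bile acid synthesis (-0.73 ± 0.16, adjusted p = 0.00485). Arg1 of the urea cycle rose (0.36 ± 0.10). Of the cell type lists, Egfl7 alone of 14 endothelial genes fell (-0.60 ± 0.14) and Ighm alone of 6 B and plasma cell genes rose (0.85 ± 0.23). Cela1 fell (-0.57 ± 0.16), the only pancreatic acinar gene tested of 15 in its list. Of 14 pericentral hepatocyte genes 1 fell, and 0 with the covariate.

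In all, 880 genes differed by mean level, 224 higher and 656 lower under arrhythmic feeding, and 252 of them by at least 1.5-fold. Genes with a mean of at least 10 CPM that changed in the same direction at each of the 6 times included Tmie (0.96 ± 0.21), Ppme1 (0.69 ± 0.15), Spc24 (0.65 ± 0.15), Arhgap32 (-0.76 ± 0.14) and Nrep (-0.75 ± 0.17). At an unadjusted p under 0.05, 3079 genes differed. Of the lists tested by mean level, cell cycle alone was called, higher under arrhythmic feeding (median log2 change 0.212, adjusted p = 0.035; adjusted p = 0.953 with an estimated correlation). Its members Cdk1 (0.81 ± 0.26), Ccnd1 (0.74 ± 0.23) and Rrm2 (0.53 ± 0.13) rose among 14 tested, and 2 members with the GC slope as a covariate, where Cdk1 was not called (adjusted p = 0.0683). Of the 5 libraries of extreme GC slope, 4 were of night-restricted replicate 1. The count was 772 with the GC slope as a covariate, 378 of them higher, and 503 were also called without it. Without the 5 libraries 95 genes differed, 38 of them higher. Car5a, a mitochondrial carbonic anhydrase, fell by mean level (-0.78 ± 0.22), and its log2 change was -0.30 with the covariate (adjusted p = 0.201). The count was 384 without night-restricted ZT06 replicate 1, 420 without night-restricted ZT22 replicate 1, and 435 without night-restricted ZT18 replicate 1. It was 476 without night-restricted ZT02 replicate 1, 566 without arrhythmic ZT22 replicate 1, and 583 without arrhythmic ZT10 replicate 3.

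Arrhythmic feeding was next compared with ad libitum feeding, in which animals time their own meals. The rhythm of 3 genes differed, all with a smaller range under arrhythmic feeding. Ppp1r3b had a range of 2.27 ± 0.30 at ZT 20.1 under ad libitum and 0.98 ± 0.30 under arrhythmic feeding (adjusted p = 0.0327). Lgalsl, a galectin-like gene, had ranges of 2.27 ± 0.21 and 1.56 ± 0.21 (adjusted p = 0.0327). Pnpla3, a lipid droplet lipase, had ranges of 4.10 ± 0.78 and 1.91 ± 0.75 (adjusted p = 0.0396). Adjusted over the list alone, the differences called were 11 of 18 in lipogenesis, 10 of 24 in cholesterol synthesis, 9 of 19 in core clock, 5 of 14 among glucocorticoid-responsive genes, 4 of 19 in glycolysis and glycogen, and 3 of 12 in clock-controlled liver output. Adjusted over all genes with the GC slope as a covariate they were 6, 2, 1, 0, 1 and 1 in that order. At an unadjusted p under 0.05, 1150 genes differed, and DESeq2 called 32. The count was 35 with the GC slope as a covariate, the 3 genes included and 8 with a larger range, and 12 without the 5 libraries of extreme GC slope.

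The count of 3 rested on single libraries. It was 0 without arrhythmic ZT22 replicate 1, ZT06 replicate 2, ZT14 replicate 2, ZT22 replicate 2, ZT14 replicate 3 or ZT18 replicate 3. It was also 0 without ad libitum ZT06 replicate 1, ZT02 replicate 2, ZT02 replicate 3 or ZT14 replicate 3. It was 1 without ad libitum ZT14 replicate 1, ZT06 replicate 2, ZT10 replicate 2, ZT06 replicate 3 or ZT10 replicate 3. It was 5 without arrhythmic ZT10 replicate 3 and 6 without arrhythmic ZT02 replicate 2.

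By mean level, genes of sex-biased expression differed between arrhythmic and ad libitum feeding. Cyp4a12a, a male-biased fatty acid hydroxylase (ENSMUSG00000066071.6, chromosome 4, 115299046 to 115332815), was at 873 ± 184 CPM under ad libitum and 488 ± 194 CPM under arrhythmic feeding (SD, n = 18), a log2 change of -0.84 ± 0.15 (adjusted p = 0.000397). Cyp4a12b, its paralog, fell (-1.06 ± 0.14, adjusted p = 2.09e-06), as did Cyp7b1, an oxysterol hydroxylase (-0.82 ± 0.20), and Susd4 (-0.68 ± 0.18). Cyp17a1, a steroid hydroxylase (ENSMUSG00000003555.7, chromosome 19, 46667165 to 46673172), rose from 12.4 ± 4.75 to 40.8 ± 28.6 CPM (1.66 ± 0.28, adjusted p = 0.000216). Cyp2b9 (ENSMUSG00000040660.6, chromosome 7, 26173411 to 26210661) rose from 4.6 ± 4.19 to 11.3 ± 7.12 CPM (1.37 ± 0.38), a call lost in 22 of 56 alternatives. Prlr, the prolactin receptor gene, rose by 0.74 ± 0.12 and Abcd2 by 1.05 ± 0.18.

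Of 15 male-biased genes, 4 fell, 0 rose and 11 were not called, 10 fell when adjusted over the list alone, and 6 with the GC slope as a covariate (median -0.385, adjusted p = 1.03e-12; adjusted p = 0.0197 with an estimated correlation and 0.0833 with the GC slope too). Of 9 female-biased genes, 4 rose, and Cyp3a41a, a female-biased P450 gene, fell (-2.14 ± 0.61), with 4 and 1 also with the covariate. Cyp3a41a had a mean of 0.516 CPM over the libraries, close to the floor. The female-biased list was higher (median 0.4, adjusted p = 0.00254; adjusted p = 0.126 with an estimated correlation). Genes of the adipocyte list also fell. Of these, Car3 had a mean of 11800 CPM over the libraries against 4.18 for Cfd, so a fall of Car3 need not reflect adipocytes. Cfd, adipsin, went from 9.03 ± 4.99 to 1.56 ± 1.33 CPM (-2.53 ± 0.36, adjusted p = 9.07e-06). Cidea, a lipid droplet protein gene (-1.93 ± 0.48), and Car3, a carbonic anhydrase (-0.53 ± 0.15), also fell, 3 of 5 markers tested and 3 with the covariate (adjusted p of the list 1.85e-05; 0.000485 as adjusted p with an estimated correlation). Amino acid catabolism and urea cycle was higher (adjusted p = 3.2e-05; adjusted p = 0.126 with an estimated correlation), with 2 of 24 called and 6 with the covariate, Asl (0.53 ± 0.14) and Sds (1.42 ± 0.41). Gluconeogenesis and fasting was higher (adjusted p = 0.00254; adjusted p = 0.156 with an estimated correlation). Its called members were Sds, which encodes a serine dehydratase, and Igfbp1, which encodes an IGF-binding protein (1.07 ± 0.29), and with the covariate 3 of 17 rose and 1 fell. Sds was also the called member of periportal hepatocytes, 1 of 13 and 5 with the covariate (adjusted p of the list 0.00883; adjusted p = 0.126 with an estimated correlation).

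**Figure D5:**
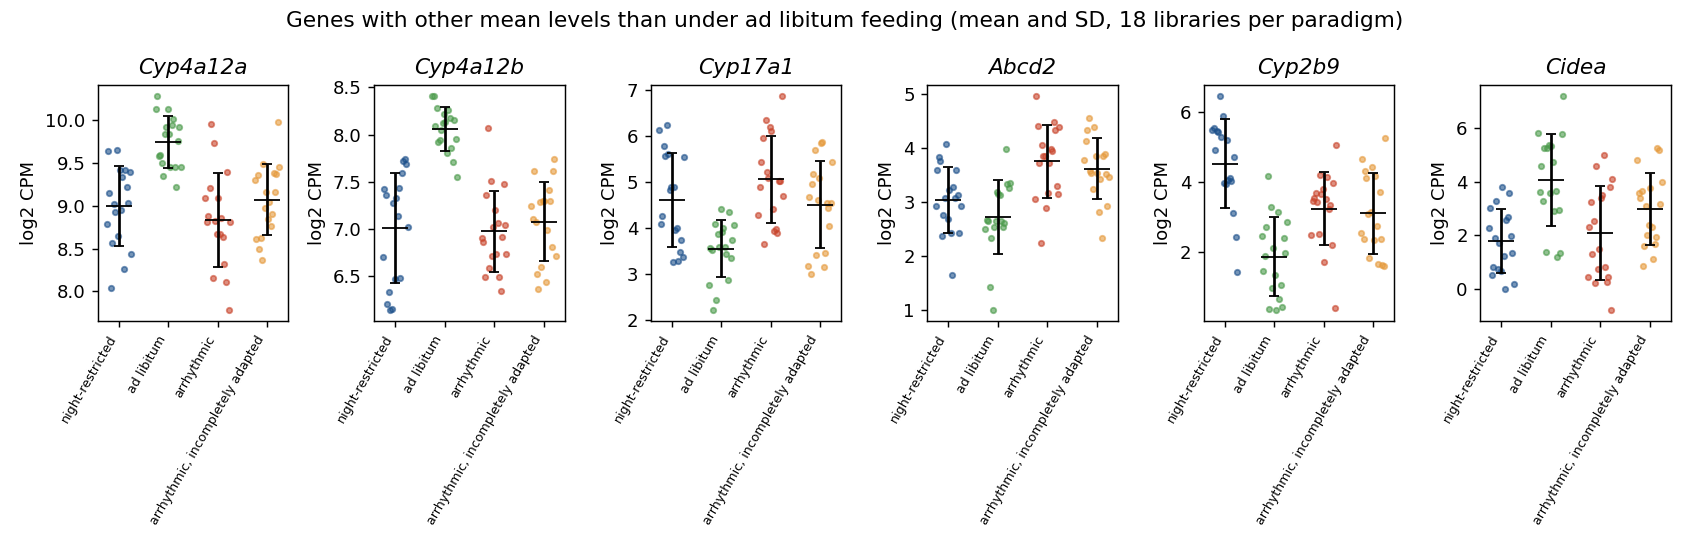
Levels of Cyp4a12a, Cyp4a12b, Cyp17a1, Abcd2, Cyp2b9 and Cidea (log2 CPM) in each library by feeding paradigm, with points for libraries and bars for the mean ± SD of 18 libraries. Cyp4a12a was at 873 ± 184 CPM under ad libitum and 488 ± 194 CPM under arrhythmic feeding.

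In all, 267 genes differed between arrhythmic and ad libitum feeding by mean level, 84 higher and 183 lower under arrhythmic feeding, 156 of them by at least 1.5-fold. Among them were Cyp39a1, an oxysterol hydroxylase (0.90 ± 0.15), Slco1a4, an organic anion transporter (0.74 ± 0.14), Hamp2, a hepcidin gene (1.23 ± 0.25), and Slc3a1 (0.88 ± 0.21). Serpina12, which encodes vaspin (-1.39 ± 0.28), and Aatk, a kinase gene (-1.04 ± 0.15), were lower. Saa1, an acute phase gene (-0.96 ± 0.27), and S100a8, a neutrophil marker (-1.17 ± 0.31), fell, and Cyp2b10, a xenobiotic-inducible P450 gene, rose (0.93 ± 0.25). At an unadjusted p under 0.05, 1782 genes differed. With the mean log2 CPM of the adipocyte markers as a covariate 7 were called, and 0 of the 15 male-biased genes. Adding the GC slope as a covariate gave 788, all 267 included, 355 of them higher and 433 lower, and 368 differed without the 5 libraries of extreme GC slope, 148 of them higher. The count was 154 without arrhythmic ZT22 replicate 1, 171 without arrhythmic ZT22 replicate 2, 174 without ad libitum ZT06 replicate 1, and 170 without ad libitum ZT10 replicate 2.

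Night-restricted and ad libitum feeding also differed in mean levels of genes of sex-biased expression. Cyp2b9 rose from 4.6 ± 4.19 to 30.5 ± 21.6 CPM (log2 change 2.80 ± 0.39, adjusted p = 2.5e-06), Cyp39a1 by 1.37 ± 0.15 (adjusted p = 2.2e-09) and Cyp17a1 by 1.24 ± 0.28. Cyp4a12a (-0.71 ± 0.15), Cyp4a12b (-0.98 ± 0.14) and Cyp7b1 (-0.92 ± 0.20) fell, the 3 called of 15 male-biased genes, with 8 when adjusted over the list alone and 4 with the GC slope as a covariate (adjusted p = 2.95e-10; adjusted p = 0.0444 with an estimated correlation and 0.0605 with the GC slope too). Adipocyte markers fell too, with Cfd (-2.62 ± 0.37) and Cidea (-2.65 ± 0.50) called of 5, and 2 with the covariate (adjusted p of the list 0.000196; adjusted p = 0.00236 with an estimated correlation). Female-biased genes were higher, with Cyp2b9, Cyp17a1 and Acot3, an acyl-CoA thioesterase (1.01 ± 0.25), called of 9, and 3 with the covariate (adjusted p = 0.00508; adjusted p = 0.179 with an estimated correlation). Cholesterol synthesis was higher as a list with 0 members called and 1 with the covariate (adjusted p = 0.00466; adjusted p = 0.568 with an estimated correlation). Cell cycle was lower (adjusted p = 0.0311, but 0.391 with an estimated correlation, and 0.0539 with the GC slope as a covariate). With the GC slope as a covariate the lipogenesis (adjusted p = 0.00262) and erythroid (0.00846) lists were also lower. The stellate cell and fibroblast list was higher there (0.0481). Each had an adjusted p of 0.338 with an estimated correlation too. Rdh16f2 (0.94 ± 0.11), Hsd17b6 (0.89 ± 0.16), Mt1 (1.21 ± 0.29), Trib3 (0.65 ± 0.18; adjusted p = 0.0582 with the covariate) and Rbm3 (0.45 ± 0.11) rose. Serpina12 (-1.58 ± 0.28), Mup18, a major urinary protein gene (-1.15 ± 0.30, a call lost in 12 of 56 alternatives), Lgals1 (-0.99 ± 0.21), Fitm1 (-0.86 ± 0.15) and Pltp (-0.75 ± 0.15) fell.

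The mean level of 206 genes differed between night-restricted and ad libitum feeding, 92 higher and 114 lower, 93 of them by at least 1.5-fold. At an unadjusted p under 0.05, 2085 genes differed. Adding the GC slope as a covariate gave 457, 198 of the 206 among them and 182 higher, and 120 differed without the 5 libraries of extreme GC slope, 33 of them higher. With the mean log2 CPM of the adipocyte markers as a covariate 5 were called. DESeq2 called 393, 215 of them higher. Of 100 assignments of the libraries to the paradigms within each time, the real one included, 5 gave as many as 206, and the highest other count was 3741. The count was 125 without night-restricted ZT02 replicate 1, 133 without night-restricted ZT18 replicate 1, and 135 without night-restricted ZT06 replicate 1. It was 334 without night-restricted ZT02 replicate 3, 351 without night-restricted ZT22 replicate 2, and 458 without ad libitum ZT10 replicate 2.

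For rhythm, edgeR called 0 genes between night-restricted and ad libitum feeding, with 1109 at an unadjusted p under 0.05. DESeq2 called 19 and limma 0, and 39 were called with the GC slope as a covariate and 0 without the 5 libraries of extreme GC slope. Alas1 peaked at ZT 13.6 under night-restricted and ZT 14.1 under ad libitum feeding (adjusted p of the rhythm difference 0.65). Tfrc had ranges of 3.50 ± 0.42 and 0.92 ± 0.39 (adjusted p = 0.0989). Adjusted over the list alone, 9 of 24 cholesterol synthesis genes, 6 of 16 heat shock protein genes, 4 of 14 glucocorticoid-responsive genes and 3 of 19 ER chaperone genes differed, and over all genes with the GC slope as a covariate 3, 1, 0 and 0 in that order. The count was 5 without ad libitum ZT14 replicate 1 or night-restricted ZT06 replicate 1, and 4 without night-restricted ZT02 replicate 3. It was 3 without ad libitum ZT18 replicate 3 or night-restricted ZT10 replicate 3. It was 1 without ad libitum ZT06 replicate 3, ad libitum ZT10 replicate 3 or night-restricted ZT06 replicate 3.

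The arrhythmic paradigms were compared to ask whether incomplete adaptation changed expression. Ppp1r3b had a range of 1.32 ± 0.30 under incompletely adapted arrhythmic and 0.98 ± 0.30 under arrhythmic feeding (adjusted p of the difference 0.942), and Mid1ip1 ranges of 0.62 ± 0.30 and 0.93 ± 0.30 (adjusted p = 0.942). For rhythm edgeR called 0 genes, with 310 at an unadjusted p under 0.05, and DESeq2 and limma called 0. For mean level edgeR called 0 genes, with 639 at an unadjusted p under 0.05, and DESeq2 and limma called 0. In either test 0 genes were called with the GC slope as a covariate, and 0 without the 5 libraries of extreme GC slope. As lists, amino acid catabolism and urea cycle was lower under incompletely adapted feeding (median -0.14, adjusted p = 2.44e-06; adjusted p = 0.0556 with an estimated correlation). Periportal hepatocytes were lower (median -0.102, adjusted p = 0.000107; adjusted p = 0.0279 with an estimated correlation and 0.0516 with the GC slope too). Erythroid cells were lower (median -0.45, adjusted p = 0.000383; adjusted p = 0.218 with an estimated correlation). Adipocytes were higher (median 0.479, adjusted p = 0.000383; adjusted p = 0.00791 with an estimated correlation and 0.0287 with the GC slope too). Adjusted over the list alone, the members called were 2, 4, 2 and 1. In genes chosen under ad libitum feeding the ratio of ranges was 1.08, and 16 of 100 assignments of the labels gave a ratio as far from 1.

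The spread between libraries, as the median SD of log2 CPM, was 0.434 ± 0.117 under night-restricted feeding (SD over the times, n = 6 times), 0.327 ± 0.0803 under ad libitum, 0.325 ± 0.0447 under arrhythmic and 0.347 ± 0.0626 under incompletely adapted arrhythmic feeding. The difference between arrhythmic and night-restricted feeding was -0.109 (exact sign-flip permutation p = 0.125, two-sided). It was -0.0121 with the GC slope removed (exact permutation p = 0.4062). The differences were 0.107 between night-restricted and ad libitum feeding (exact permutation p = 0.1875), -0.0017 between arrhythmic and ad libitum feeding (exact permutation p = 1) and 0.0216 between the arrhythmic paradigms (exact permutation p = 0.75).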

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

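The tests of GC content on the libraries' main axis, of the GC slope on the counts and on the male-biased genes, of adipocyte markers on single male-biased genes, and of replicate 1 of night-restricted feeding were chosen after the results were seen.

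The rhythm of 495 genes differed between arrhythmic and night-restricted feeding, which is a difference between groups under the same test of rhythm. Of 100 assignments of the libraries to the paradigms within each time, the real one included, 1 gave as many, and the highest other count was 3. This argues against a chance assignment of single libraries. The assignments did not keep libraries of like replicate number together. With the GC slope as a covariate 1 of 100 gave the 424 genes of the real assignment, and the highest other count was 7.

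The rhythm of 3 genes differed between arrhythmic and ad libitum feeding, likewise a difference between groups. Of 100 assignments 1 gave as many and the highest other count was 2. With so small a margin chance is not excluded. The count was also 0 with no filter and rested on single libraries.

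The first pattern was that libraries differed along a main axis. Its correlation with the GC slope was 0.949. Library size did not follow it (r = -0.0713), and paradigm and time together held 33.9 percent of the variance of the GC slope, where permuted labels held a median of 32 percent (permutation p = 0.405). The 4 paradigms alone held 9.01 percent, where permuted labels held a median of 3.37 percent (permutation p = 0.0839). These values argue against library size as its cause. A p above 0.05 does not exclude the paradigms or times, so these stay open. The GC slope is estimated from the same expression values, so the axis may come from sample handling or library preparation, and what set it was not tested.

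The second pattern was that more genes were called rhythmic under night-restricted than under arrhythmic feeding, by a ratio of counts of 8.86. The ratio was 5.17 with the GC slope as a covariate, 4.67 with each paradigm fitted alone, 9.31 with all libraries thinned to 4342026 counts, and 4 without night-restricted replicate 1. Each stayed above 1.5, which argues against the GC slope, a shared estimate of the spread, library size, or that replicate as the whole cause. The drops to 5.17, 4.67 and 4 leave a part open to the GC slope, the shared estimate of the spread and replicate 1. The fits behind 4.67 and 4 also used fewer libraries, which can lower a count by itself. Leaving out any replicate number of night-restricted feeding gave 2242 to 2842 genes, against 3801. Without replicate 1 the arrhythmic count went from 429 to 561. Whether the timing of food intake is the cause was not tested by these values.

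The third pattern was that male-biased liver genes were lower than under ad libitum feeding. Under arrhythmic feeding their median log2 change was -0.385 (median SE 0.15, 4 called), and it was -0.359 with the GC slope as a covariate (median SE 0.141, 6 called). With the adipocyte markers as a covariate it was -0.426 (median SE 0.2), and 0 genes were called. The SE grew in all 15 genes and the change shrank in 8. For Cyp4a12b it went from -1.06 ± 0.14 to -0.753 ± 0.172 (adjusted p = 0.0506), for Cyp4a12a from -0.839 ± 0.149 to -0.551 ± 0.184. Over all genes the calls went from 267 to 7. Under night-restricted feeding the male-biased median went from -0.443 to -0.392 (median SE 0.199) and its calls from 3 to 0, and the female-biased median from 0.305 to 0.184. Over all genes the calls there went from 206 to 5. The female-biased median under arrhythmic feeding went the other way, from 0.4 to 0.49. The median under arrhythmic feeding with the GC slope argues against the GC slope as the whole cause. The adipocyte covariate cannot decide on adipose tissue. The markers themselves differed between the paradigms, the covariate widened the SE and removed most calls, and Car3, at 11800 CPM, was among its markers. Adipose tissue in the ad libitum libraries therefore stays open as a cause. With the GC slope and an estimated correlation together the adjusted p of the list was 0.0833 under arrhythmic and 0.0605 under night-restricted feeding, so the list was not called there. A biological cause was not tested.

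For rhythmic genes within a paradigm, 1 of 100 assignments of times gave as many under each of the 4 paradigms, the fewest that 100 can give. The highest other counts were 3196 against 3801 under night-restricted, 82 against 951 under ad libitum, 36 against 429 under arrhythmic and 444 against 462 under incompletely adapted arrhythmic feeding. These values argue against a chance assignment of times under ad libitum and arrhythmic feeding. Under night-restricted and incompletely adapted feeding an assignment came close to the real count, so chance is not excluded for counts of that size. With the GC slope as a covariate the night-restricted count was 4226 and the highest other 1275, with 1 of 100 as large. Times were not reassigned with the covariate in the other paradigms. For mean level, 1 of 100 gave as many between arrhythmic and night-restricted feeding (880, highest other 832). With the GC slope as a covariate these were 772 and 16, also 1 of 100. Between arrhythmic and ad libitum feeding 1 of 100 gave as many (267, highest other 3). The assignments moved single libraries, while libraries of like replicate number in a paradigm went together over times (median correlation 0.242). Chance at the level of such sets is therefore not excluded. Without a replicate number of a paradigm the counts ran from 181 to 2593 and from 52 to 723, in that order. Between night-restricted and ad libitum feeding 5 of 100 gave as many (206, highest other 3741), so chance cannot be excluded. An assignment calling several times the real count points to a structure of the samples. A count of 0 is met by any assignment, so nothing follows for the rhythm count of 0 between these paradigms (100 of 100, highest other 1839). The same holds for the counts of 0 between the arrhythmic paradigms (100 of 100 for both, highest other 3 for rhythm and 490 for mean level).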

How the results depend on the processing

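The GC slope covariate, the libraries left out for it, single libraries left out and the authors' gene set were tests chosen after seeing the data. The cause was not tested for the values below, except that fewer libraries were fitted where libraries were left out. Replicate numbers did not pair libraries across paradigms, as over 108 pairs of like time and number the median correlation was 0.0104, with 38 over 0.1. Within a paradigm 180 pairs of like number at other times had a median of 0.242 (127 over 0.1), against -0.116 for other numbers. The replicate number as a block was shared across paradigms, so it cannot take up a tie within a paradigm. With this block 3866, 971, 443 and 463 genes were rhythmic under night-restricted, ad libitum, arrhythmic and incompletely adapted arrhythmic feeding. These counts therefore do not show whether that tie matters.

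Rhythmic genes under night-restricted feeding (3801) were 1860 in a fit of those libraries alone and 1741 with time as a factor. Under ad libitum feeding (951) they were 509 with time as a factor, 1511 with the GC slope, 1514, 1503 and 1494 with it from the last 100, 200 and 500 bases, 1610 with it and the replicate number, and 1522 without the extreme libraries. Under arrhythmic feeding (429) they were 212 with time as a factor, 817 with the GC slope, 851, 831 and 810 by window, and 893 with the replicate number. Under incompletely adapted arrhythmic feeding (462) they were 300, 829, 861, 844, 814 and 892 in that order.

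Rhythm differences between arrhythmic and night-restricted feeding (495) were 248 with no filter, 313 without the extreme libraries, 257 in a fit of those libraries alone, 759 with limma, 52 with time as a factor and 949 with DESeq2. Between arrhythmic and ad libitum feeding (3) they were 0 with no filter, 35 with the GC slope, 40, 35 and 33 by window, 45 with the replicate number, 12 without the extreme libraries, 13 in a fit of those libraries alone and 32 with DESeq2. Between night-restricted and ad libitum feeding (0) they were 4 at a mean of at least 10 CPM, 39 with the GC slope, 50, 41 and 38 by window, 54 with the replicate number and 19 with DESeq2.

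Mean differences between arrhythmic and night-restricted feeding (880) were 389 with no filter, 95 without the extreme libraries, 562 in a fit of those libraries alone and 252 at 1.5-fold or more. Between arrhythmic and ad libitum feeding (267) they were 143 with no filter, 173 at a mean of at least 10 CPM, 788 with the GC slope, 863, 810 and 780 by window, 909 with the replicate number and 156 at 1.5-fold or more. Between night-restricted and ad libitum feeding (206) they were 128 with no filter, 457 with the GC slope, 511, 485 and 431 by window, 523 with the replicate number, 120 without the extreme libraries, 132 in a fit of those libraries alone, 393 with DESeq2 and 93 at 1.5-fold or more. Between the arrhythmic paradigms (0) the count was 1 with the replicate number as a block.

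Genes rhythmic in all 4 paradigms (196) were 107 at a false discovery rate of 0.01 and 381 with the GC slope. The spread difference between arrhythmic and night-restricted feeding was -0.0121 with the GC slope removed. Lists called by mean level for arrhythmic against night-restricted feeding (1) were 3 with the GC slope, and 0 with an estimated correlation, also with the GC slope or the block. For arrhythmic against ad libitum (6) and night-restricted against ad libitum feeding (5) they were 2 with an estimated correlation, 2 with the block too and 1 with the GC slope too. For the arrhythmic paradigms (4) they were 9 with the GC slope, 2 with an estimated correlation, 2 with the block too and 1 with the GC slope too.

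Some range differences changed sign. The Lect2 range difference arrhythmic against night-restricted was -0.015 with DESeq2 size factors, -0.019 in the authors' gene set, -0.057 with limma, -0.068 at a mean of at least 10 CPM, -0.032 with no filter, -0.00427 in a fit of those libraries alone and -0.064 with upper quartile scaling. The Srsf2 range difference arrhythmic against night-restricted was 0.033 with limma and 0.12 with time as a factor. The Thrsp range difference arrhythmic against night-restricted was -0.54 with the GC slope, -0.66, -0.59 and -0.48 by window and -0.56 with the replicate number.

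Leaving out a replicate number of a paradigm or a single library gave 2242 to 4722 rhythmic genes under night-restricted, 253 to 1300 under ad libitum, 180 to 441 under arrhythmic and 183 to 596 under incompletely adapted arrhythmic feeding. Rhythm differences ranged from 100 to 1250 between arrhythmic and night-restricted, 0 to 6 between arrhythmic and ad libitum, 0 to 11 between night-restricted and ad libitum feeding and 0 to 2 between the arrhythmic paradigms. Mean differences ranged from 181 to 2593, 52 to 723, 65 to 1740 and 0 to 99 in that order. The ratio of ranges of the arrhythmic paradigms ran from 0.997 to 1.19. Lists called by mean level ran from 0 to 4 for arrhythmic against night-restricted, 4 to 10 for night-restricted against ad libitum feeding and 2 to 8 for the arrhythmic paradigms. The Lect2 range difference arrhythmic against night-restricted ran from -0.21 to 0.16 and the Msmo1 range difference arrhythmic against night-restricted from -0.0534 to 0.40. The ratio of ranges of arrhythmic to night-restricted feeding stayed between 0.498 and 0.674 with replicate numbers left out, and the number of clock genes rhythmic in all 4 paradigms ran from 12 to 16. Of 50 simulated genes with a rhythm difference of a log2 range of 1 between arrhythmic and night-restricted feeding 0 were called. With few simulated genes changed, this count need not hold for the real data.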

Other observations

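The test of the GC slope against mitochondrial counts was chosen after seeing the data.

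Nop58, a nucleolar protein gene, had a range of 1.19 ± 0.25 under night-restricted and 0.33 ± 0.25 under arrhythmic feeding (adjusted p of the difference 0.0194). Of 25 ribosome biogenesis genes 10 were rhythmic under night-restricted, 2 under ad libitum and 0 under either arrhythmic paradigm (15, 2, 0 and 2 in the 4 paradigms with the GC slope as a covariate). The rhythm of 3 of them differed between arrhythmic and night-restricted feeding (1 with the GC slope as a covariate) and of 0 between arrhythmic and ad libitum feeding. Of 26 respiratory chain genes 5 were rhythmic under night-restricted feeding and 0 in the others (7, 0, 1 and 0 with the covariate). Of 24 genes of amino acid catabolism and urea cycle 9, 2, 5 and 1 were rhythmic in the 4 paradigms (11, 8, 7 and 3 with the covariate), and of 20 genes of bile acid and xenobiotic metabolism 9, 4, 3 and 5 (10, 10, 6 and 8 with the covariate).

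Of 13 Kupffer cell and macrophage markers 3 and 2 were rhythmic under night-restricted and ad libitum feeding and 0 in the others (3 and 4 when adjusted over the list alone, 1 and 4 with the GC slope as a covariate). Of 14 endothelial markers 2 were rhythmic under night-restricted, 0 under ad libitum and 1 under arrhythmic feeding (7, 0 and 1 when adjusted over the list alone, 3, 0 and 1 with the covariate). The adipocyte markers tested were at means of 11800 CPM for Car3, 12.9 for Fabp4, 13.3 for Cidea, 4.18 for Cfd and 2.94 for Adrb3, so that Car3 lies far above the others.

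The GC slope also followed the percent of mitochondrial counts over the 72 libraries, with Pearson r = -0.9 and Spearman rho = -0.85 (permutation p = 1e-05 for both, the smallest these permutations can give; Benjamini-Hochberg adjusted over 11 relations, 1.2e-05 and 1.4e-05). Without the 2 libraries farthest out r was -0.876. Within night-restricted, ad libitum, arrhythmic and incompletely adapted arrhythmic feeding r was -0.956, -0.918, -0.818 and -0.945.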
